A study of Mus musculus with 28 samples.

How the data were processed

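Per the sample labels, RNA was measured in LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction of mouse bone marrow that holds stem and multipotent progenitor cells, from 6 libraries labelled Setd2 KO and 6 labelled WT. Per the labels' protocols, whole bone marrow was depleted with antibodies against CD3, Gr1, Ter119 and B220, the remaining cells were sorted on cKit and Sca1, RNA was isolated with Qiagen kits, and libraries were amplified with a SMARTer low-input kit. The series design text instead speaks of early proB cells for its RNA-seq, and this conflict was not resolved: the sample labels, which give the LSK sort in detail, were followed. The series also lists 4 ATAC-seq and 12 ChIP-seq samples, which were not analysed here.

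The deposited table holds raw counts per gene symbol, with 1 column per library and no normalization. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1 and DESeq2 were used with the mouse build mm9, and the gene annotation and the strand setting are not given in the sources used here. The kit is not known from the labels to mark strand, so reads of a gene and of a gene overlapping it on the other strand may not have been told apart. HTSeq leaves out reads that align to several places, so values of near-identical genes are uncertain, among them the globin, histone, protocadherin and zinc finger genes. The table ends in 5 summary rows, which were kept out of library sizes and tests. Of the uniquely aligned reads, 21.8% to 28.8% per library fell in no annotated gene and 3.28% to 3.99% were ambiguous between genes. The row of alignments to several places held 19407546 to 59611203 per library, and the other 2 summary rows were 0 throughout.

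Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F-test with robust dispersion, genotype as the only term). P-values were adjusted by the Benjamini-Hochberg method over all 16862 tested genes of the 34620 in the table, with a threshold of 0.05. Every adjusted p of a gene given without another tool's name is from this test. Levels are CPM (counts scaled to a common library size) after TMM scaling, given as mean ± SD over 6 libraries. Nothing in the labels says that the libraries came from separate mice, so p-values measure the spread between these libraries, which may be in part technical.

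Before the data were examined, 31 gene lists were fixed. The 29 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, with camera using a correlation estimated per list, and with fry. Of the other lists, the mitochondrially encoded genes had too few tested members, and the Y-linked genes and Xist served as a check of the sexes. The rule for named genes was fixed at the same time. It names Setd2, the sort and depletion antigens and Flt3, then the 10 largest changes per direction among genes past the threshold with a mean of at least 5 CPM in 1 group and at least 5 of 6 libraries of each group on their side of the median. It adds the 4 members with the smallest p from each list that was called or had at least 3 members past the threshold, and 2 from each other list. Predicted genes were passed over among the largest changes, 2 higher and 1 lower.

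The alternatives were DESeq2 1.42.0, other scalings and filters, limma-voom, a surrogate variable from sva 3.50.0, covariates and libraries left out. Gene names and gene order were taken from a table of the assembly GRCm38.p6, which differs from the build of the counts, so no coordinates are given. It matched 15786 of the tested symbols. In simulated counts for these libraries, 200 of 16862 genes were changed, drawn from those with a mean of at least 1 CPM. Of these, 49.3% of genes changed 1.5-fold, 91.0% changed 2-fold and 97.0% changed 4-fold were recovered, and 2.47% of calls were false. In the data 6074 genes were called, so these shares need not hold for the reported test. They do not cover genes with a lower mean.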

Results

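Setd2 encodes the methyltransferase that trimethylates lysine 36 of histone H3. The series concerns its part in lymphoid and neural development, and the libraries analysed here compare RNA of bone marrow cells labelled LSK, from Setd2 KO (n = 6) and WT (n = 6). The series design text speaks of early proB cells for RNA-seq, so the cell identity used throughout is that of the sample labels. Counts assigned to genes ranged from 25836378 (KO 4) to 67812886 (KO 5) in KO and from 42175959 (WT 1) to 76930919 (WT 6) in WT libraries, and the depth did not differ between genotypes by more than the spread (exact permutation test, two-sided, p = 0.405). The first principal component of log2 CPM held 44.3% of the variance and separated the genotypes, and KO 5 lay apart on the second, which held 10.2%. Correlations of log2 CPM were 0.975 to 0.989 within genotypes and 0.956 to 0.974 between them, across genes, which are not independent replicates.

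**Figure D1:**
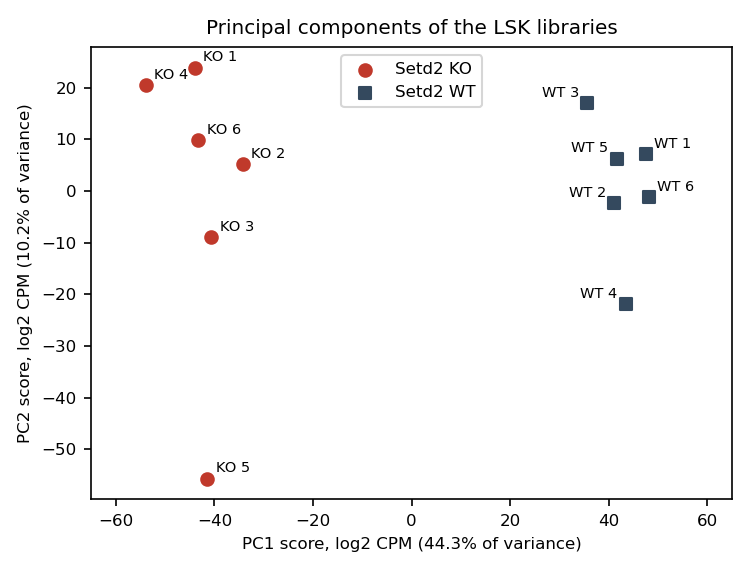
Scores of the 12 LSK libraries on the first and second principal components of log2 CPM, with 1 point per library, circles for Setd2 KO and squares for WT. The first component (44.3% of the variance) parts the 6 KO from the 6 WT libraries, and KO 5 lies away from the other KO libraries on the second (10.2%).

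Setd2 itself stood at 117 ± 8.73 CPM in KO and 130 ± 9.62 CPM in WT libraries (SD, n = 6 each). KO libraries lay between 107 and 132 CPM and WT libraries between 115 and 140 CPM. The log2 fold change was -0.16 ± 0.075 (SE), which did not pass the test (adjusted p = 0.106, edgeR quasi-likelihood). A count over the whole gene cannot show the loss of single exons, so these values do not check the genotype labels. Setd2 passed the threshold with library size as the only scaling (log2 fold change -0.26, adjusted p = 0.0217), with limma-voom, and without KO 1 or without WT 6, and stood at -0.05 (adjusted p = 0.649) with the share of reads in no gene as a covariate, an alternative added after seeing the data.

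Among the antigens used for sorting, Ly6a, which encodes Sca-1, fell 2.91-fold in KO, from 86.7 ± 11.2 to 29.8 ± 6.32 CPM (adjusted p = 3.01e-07, apart in 6 of 6 libraries of each group). Kit stood at 1330 ± 268 CPM in KO and 1149 ± 109 CPM in WT and did not pass (adjusted p = 0.195), nor did Ptprc, which encodes CD45 (log2 fold change -0.23, adjusted p = 0.0754). Kit passed with limma-voom, without KO 5, and without KO 4 and KO 5 together, the last chosen after seeing the data. Ptprc passed with library size as the only scaling and without KO 1. Cd3e, with 28 counts over each group, and Ly6g, with 23 in KO and 30 in WT, were under the filter, and Ly76 is not a symbol of the table. Xist and Y-linked reads showed 3 KO and 3 WT libraries with Y-linked reads and 3 of each without, so the sexes were balanced.

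In all, 6074 of 16862 tested genes (36.02%) differed between the genotypes, 3020 higher and 3054 lower in KO. Of these, 843 were higher and 563 lower by at least 2-fold. In 17.8% of tested genes all KO libraries lay on 1 side of all WT libraries, where chance gives 0.216%. With library size as the only scaling, 2270 genes were higher and 4125 lower, and the median log2 fold change of all tested genes moved from -0.01 to -0.11.

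The largest increases were in Cda, cytidine deaminase, which rose 118-fold from 0.0747 ± 0.0250 to 8.995 ± 2.55 CPM, and in Sfrp4, a secreted Wnt modulator, which rose 66.5-fold to 42.6 ± 6.56 CPM (adjusted p = 7.40e-10 and 1.38e-08). Ugt8a, a galactosyltransferase of sphingolipid synthesis, rose 51.2-fold, and Slc4a1, the anion exchanger of red cells, rose 49.4-fold to 54.8 ± 37.3 CPM. Tspan12, Apol8, Podxl, Gzmb, Hba-a1 and Olfm4 rose by 26.3-fold to 14.5-fold. WT 4 decided part of these values: without it Slc4a1 was 94.2-fold and Hba-a1 24.5-fold higher, and KO 2 (5.84 CPM) lay below WT 4 (11.7 CPM) in Hba-a1. With limma-voom, which kept WT 4, Slc4a1 was 125-fold higher. The largest decreases were in Zik1, a zinc finger gene, which fell 15.4-fold from 22.8 ± 1.38 to 1.44 ± 0.607 CPM (adjusted p = 4.26e-09), in Sema3d, a semaphorin, which fell 14.8-fold, and in Il17re, an interleukin 17 receptor chain, which fell 12.8-fold. Nsg1, Bdh2, Nkx2-3, Emp1, Zfp773, Myl10 and Ccr9 had log2 fold changes from -3.49 to -2.68. Myl10, at 39.2 ± 32.0 CPM in WT, lost its call without KO 4 and KO 5 and with the share of reads in no gene as a covariate, both chosen after seeing the data.

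**Figure D2:**
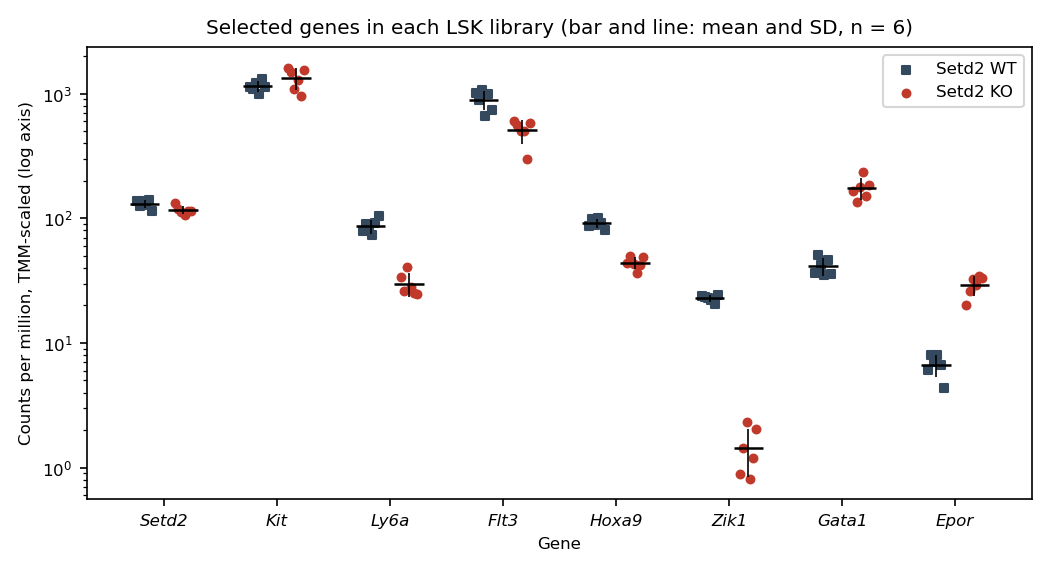
TMM-scaled CPM of 8 genes in each LSK library on a log axis, squares for WT and circles for KO, with the mean as a horizontal bar and the SD as a vertical line (n = 6). Setd2 and Kit overlap between the genotypes, Ly6a, Flt3, Hoxa9 and Zik1 lie lower in KO, and Gata1 and Epor lie higher.

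Erythroid genes rose together. Of 27 tested members of the list, 24 rose and 1 fell, with a median log2 fold change of 2.397, and the counts adjusted over the list alone were the same. Gata1, the transcription factor of the erythroid and megakaryocyte lineages, rose 4.24-fold to 175 ± 34.9 CPM, Epor, the erythropoietin receptor, rose 4.38-fold to 29.3 ± 5.42 CPM, and Tfrc, the transferrin receptor, rose 3.42-fold to 356 ± 55.8 CPM. Mt2, a metallothionein, rose 14.1-fold. Nfe2 was the member that fell (log2 fold change -0.28). Of 12 genes of heme synthesis, 9 rose and none fell, also adjusted over the list alone, among them Cpox (5.46-fold), Slc25a38 (2.79-fold) and Hmbs (2.38-fold). The erythroid and heme lists were called by camera (adjusted p = 6.88e-17 and 3.58e-06) but not with an estimated correlation (adjusted p = 0.135 for both).

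Many mitotic genes and some replication genes rose as well. Of 32 mitotic genes 21 rose and none fell (24 and 0 adjusted over the list alone), including Ccnb1, cyclin B1, at 2.09-fold, and Kif20a, a mitotic kinesin, at 1.94-fold. Of 34 replication genes 14 rose and 2 fell (16 and 2 adjusted over the list alone), among them Ccne1, cyclin E1, at 2.81-fold, and Rrm2, a ribonucleotide reductase subunit, at 2.37-fold. Their camera adjusted p were 1.14e-09 and 0.000772, and with an estimated correlation the adjusted p were 0.135 and 0.608. Replication-dependent histone genes went the other way: of 53 tested, none rose and 29 fell (31 adjusted over the list alone), with Hist1h2bg falling 2.19-fold and Hist1h1c 2.02-fold (camera adjusted p = 2.90e-09, adjusted p = 0.267 with an estimated correlation). Their list mean was low, 0.78 to 1.35 log2 CPM in WT libraries against 6.74 to 7.16 for the replication list. How fully the kit captures histone RNA is not known here, so their fall need not reflect total histone RNA. The replication list lost its call with the share of reads in no gene as a covariate, an alternative added after seeing the data. Its mean in WT 6 (7.16 log2 CPM) lay above that of KO 1, KO 2, KO 3 and KO 6 (7.05 to 7.16).

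Of 26 genes of stem cells and self-renewal, 13 fell, 3 rose and 10 did not pass (17 fell and 3 rose adjusted over the list alone). Hoxa9 fell 2.07-fold from 91.1 ± 7.80 to 44.1 ± 5.01 CPM, Hlf, a transcription factor of stem cells, fell 1.88-fold, and Nkx2-3 fell 9.71-fold, while Slamf1, which encodes CD150, rose 2.12-fold and Tek and Mllt3 rose by 0.85 and 0.60 on the log2 scale. Of 16 Hox genes and cofactors 10 fell and none rose (11 adjusted over the list alone), Hoxa5 by 3.33-fold, Hoxa7 by 1.98-fold and Hoxa10 by 2.01-fold. The camera adjusted p were 0.000861 and 6.50e-05, and with an estimated correlation the adjusted p were 0.267 and 0.173.

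Lymphoid genes moved both ways. Of 33 genes of lymphoid priming, 12 fell and 5 rose, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.214). Flt3, a cytokine receptor of multipotent progenitors, fell 1.76-fold from 897 ± 163 to 508 ± 111 CPM, Dntt, terminal deoxynucleotidyl transferase, fell 1.72-fold, and Ccr9 fell 6.40-fold. Ebf1, a B-lineage transcription factor, rose 8.22-fold to 5.46 ± 1.75 CPM, Sell, L-selectin, rose by 0.59 on the log2 scale, and Gata3 rose 1.61-fold. Among 13 B cell genes 3 rose and 3 fell. Fcrla and Spib were higher but low in level (1.28 ± 0.252 and 0.586 ± 0.233 CPM in KO), and Cd37 was lower (107 ± 11.6 CPM in KO). Among 19 T and NK cell genes 8 rose and 3 fell (9 and 3 adjusted over the list alone). The 8 were Xcl1 and Cd2, each under 1 CPM, and Ncr1, Il2rb, Klrk1, Klrb1c, Ccl5 and Cd8a. The 3 were Lck, Itk and Cd4.

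Myeloid lists were not called by camera in the reported test. Of 30 granulocyte and monocyte genes 12 rose and 2 fell (12 and 4 adjusted over the list alone), with F13a1 at 3.93-fold and Mpo, myeloperoxidase, rising 1.87-fold to 6877 ± 1153 CPM (camera adjusted p = 0.126). Lyz2 and Csf3r were the 2 that fell (log2 fold changes -0.71 and -0.53). Camera called this list in 4 alternatives: with no filter, and without KO 6, WT 4 or WT 5. Among 20 mast cell, basophil and eosinophil genes 3 rose and 5 fell: the basophil proteases Prss34 and Mcpt8 fell 4.24-fold and 3.68-fold, while Gzmb rose 18.0-fold. Among 24 megakaryocyte genes 3 rose and 5 fell, with Mpl, the thrombopoietin receptor, falling 1.99-fold and Plek 1.71-fold. Among 27 dendritic cell and macrophage genes 2 rose and 3 fell, and among 20 stromal and endothelial genes 4 rose and 4 fell. Median and mean differed in sign in the mast cell list, and camera and fry in the megakaryocyte and stromal lists.

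**Figure D3:**
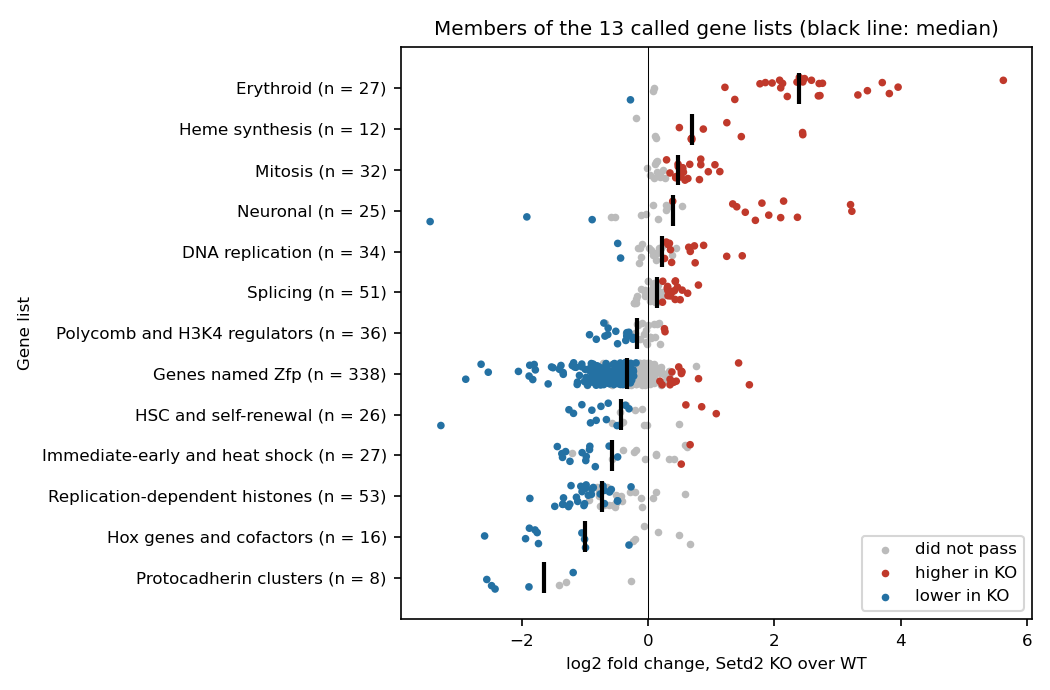
Log2 fold change (Setd2 KO over WT) of each tested member of the 13 gene lists called by camera, with 1 point per gene, coloured by whether it passed the test, and a black line at the list's median. The erythroid list has the highest median (2.397) and the protocadherin list the lowest (-1.64), and no list was called with an estimated correlation.

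Zinc finger genes fell widely. Of 338 tested genes named Zfp, 168 fell and 15 rose (178 and 18 adjusted over the list alone), with a median log2 fold change of -0.34. Zfp773 fell 7.39-fold, Zfp954 fell 3.69-fold from 31.5 ± 1.91 to 8.54 ± 1.67 CPM, and Zfp772 and Zfp456 fell 3.54-fold and 2.60-fold. Of 8 clustered protocadherin genes 5 fell and none rose (7 adjusted over the list alone), all named members being at or under 2.15 CPM. The mean log2 fold change of the protocadherin list, -1.69, was -2.36 without KO 1, -2.35 without KO 2 and -2.32 without WT 5, where more members passed the filter. The camera adjusted p were 1.11e-12 and 0.00228, and with an estimated correlation the adjusted p were 0.135 and 0.140.

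Chromatin, splicing and neuronal lists were also called. The Polycomb and H3K4 list of 36 genes also holds other chromatin genes, the Tet genes and Dot1l. Of its members 14 fell and 2 rose, also adjusted over the list alone, with Tet1 falling 1.76-fold and Bmi1 having a log2 fold change of -0.68 (camera adjusted p = 0.0220, adjusted p = 0.304 with an estimated correlation). Of 51 splicing genes 19 rose and none fell, also adjusted over the list alone, with Hnrnpa1 at 1.74-fold (camera adjusted p = 0.00119, adjusted p = 0.173 with an estimated correlation). Of 25 neuronal genes 12 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.00952, adjusted p = 0.240 with an estimated correlation). Ncam1, a cell adhesion molecule also made by some blood cells, rose 3.25-fold to 61.6 ± 17.2 CPM, Tubb3 and Ank2 rose to 4.62 ± 1.85 and 1.99 ± 0.613 CPM, and Nefh fell 3.78-fold. Of 27 immediate-early and heat shock genes 13 fell and 2 rose (14 and 3 adjusted over the list alone), with Jun falling 2.56-fold and Hsp90aa1 rising 1.59-fold (camera adjusted p = 0.0370, adjusted p = 0.748 with an estimated correlation). This was the only list called by camera that fry did not call (fry adjusted p = 0.0768). The neuronal call was lost with a filter of 1 CPM, the Polycomb call with the share of reads in no gene as a covariate, and the immediate-early call in 11 alternatives.

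The remaining lists were not called by camera in the reported test, and fry called the imprinted genes (adjusted p = 0.000252, higher). With alternatives camera called the interferon list in 3 settings, the ribosomal list in 1 and the cholesterol list in 1 (mean log2 fold change -0.28, adjusted p = 0.0197, with the share of reads in no gene as a covariate). Among 31 genes that write, erase or read H3K36 methylation 2 rose and 7 fell (2 and 6 adjusted over the list alone), and among 34 genes of V(D)J recombination and DNA repair 3 rose and 5 fell (3 and 4 adjusted over the list alone). Of 25 imprinted genes 9 rose and 2 fell, with Grb10 at 2.52-fold and Mcts2 and Nespas, which overlap other genes, at 3.61-fold and 2.19-fold. Of 29 p53 targets 8 rose and 6 fell (9 and 6 adjusted over the list alone), with Pmaip1 at 3.26-fold. Of 37 interferon-stimulated genes 1 rose and 6 fell, of 22 glycolysis genes 5 rose and 4 fell, of 22 cholesterol synthesis genes 1 rose and 2 fell (1 and 1 adjusted over the list alone), and of 83 ribosomal protein genes 15 rose and 3 fell (12 and 3 adjusted over the list alone). Median and mean differed in sign for the p53 targets, and camera's direction differed from the mean in the cholesterol list.

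The share of reads ambiguous between genes was 3.76% ± 0.161 in KO and 3.48% ± 0.116 in WT libraries, and the 10 most abundant genes took 4.67% ± 0.348 and 4.07% ± 0.202 (exact permutation test, two-sided, p = 0.00433 for each, 0.0108 adjusted over 5 library measures). Reads in no gene made up 24.8% ± 1.87 in KO and 27.1% ± 1.64 in WT (exact permutation p = 0.0519, adjusted 0.0866). By the extents of genes in GRCm38.p6, 52 of the 132 named genes overlap another gene, and their values are uncertain to that extent.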

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

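The values below lay apart from the other 5 libraries of their group, by a gap that, as a share of the group's range on the log2 scale, exceeded Dixon's 95% critical value. Of 330 groups of values tested, 19 did so, where chance gives about 1 in 20, or 16.5, so their number is near that of chance. On the CPM scale 20 did so.

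KO 5, which lay apart on the second principal component, was below the other KO libraries in Flt3 (298 CPM), Mpl (133 CPM), Il17re (0.616 CPM), Hoxa7 (13.7 CPM) and Xpc (193 CPM). KO 4, the library with the fewest counts, was above the others in Aldoa (2051 CPM) and in the mean of the cholesterol synthesis list (5.46 log2 CPM). KO 3 was above the others in Mcpt8 (134 CPM) and Cd37 (130.2 CPM), and KO 2 below them in Pcdhb22 (0.0348 CPM).

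WT 6 was above the other WT libraries in Ldha (1111 CPM) and in the mean of the DNA replication list (7.16 log2 CPM), and below them in Ppbp (0.881 CPM). WT 3 was above the others in Mcts2 (4.93 CPM) and below them in Cda (0.0307 CPM) and Dhcr24 (10.3 CPM). WT 5 was above the others in Mpo (4937 CPM), WT 1 in Nespas (2.46 CPM), and WT 4 below them in Gtse1 (25.1 CPM).

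Outside the gene counts, the share of reads ambiguous between genes was 3.76% in KO libraries, above the 3.48% of WT libraries.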

How the results depend on the processing

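The settings without KO 4 and KO 5 and with the share of reads in no gene as a covariate were chosen after seeing the data. The number of genes changed was 6074 in the reported test, 1406 with a fold of at least 2, 6663 with DESeq2, 7257 with limma-voom and 4571 with the share of reads in no gene as a covariate, which kept 67.4% of the 6074 and was not balanced between genotypes. Leaving out 1 library gave 5359 to 6406 genes, 2692 to 3134 higher and 2667 to 3272 lower, and without KO 4 and KO 5 there were 5653. The labels do not say that the replicate numbers pair the samples, and expression gave no sign of it. Deviations of same-numbered libraries correlated between -0.13 and 0.09, and 1 KO and 1 WT library correlated best with its own number. A pairing that leaves no such sign is not excluded. With the number as a replicate block 5169 genes changed, 5027 of them among the 6074, all in the same direction, and Setd2 was at -0.16. Setd2 passed the threshold with library size only (-0.26) and limma-voom (-0.17), ranged from -0.20 to -0.14 with 1 library left out, and was -0.12 without KO 4 and KO 5 and -0.05 with the share of reads in no gene. Camera called 12 to 15 lists with 1 library left out, 13 with the replicate block, 10 with the filter of 1 CPM, where the protocadherin list had too few members to be tested, 11 with the share of reads in no gene, 0 with an estimated correlation and 13 with fry, 12 of them shared. Of 1172 values of named genes under planned settings, 1164 kept direction and side, and none turned direction. Camera's direction turned in 30 list values, of lists not called in the reported test. Mean log2 fold changes were, for cholesterol synthesis, -0.0202 with DESeq2, -0.132 with library size only, -0.0458 with no filter, -0.0849 with limma-voom, -0.0422 with the replicate block, -0.0774 with the surrogate variable, -0.0354 with Y-linked reads, -0.152 without KO 4 and KO 5, and -0.285 with the share in no gene, the 1 turned value past the threshold. They were 0.0631, 0.0367 and -0.00819 for megakaryocyte genes (DESeq2, limma-voom, surrogate variable), 0.217 and 0.00072 for stromal genes (DESeq2, filter of 1 CPM), -0.248, -0.0572 and 0.396 for dendritic cell genes (library size only, without KO 4 and KO 5, share in no gene) and -0.0510 for glycolysis (share in no gene). With 1 library left out they ranged from -0.0509 to 0.106 (megakaryocyte), -0.287 to 0.0789 (dendritic), 0.0833 to 0.345 (stromal) and -0.125 to 0.0242 (cholesterol). The cause was not tested. The correction for gene length and GC content was not run. In simulated counts with 200 genes changed, each with a mean of at least 1 CPM, about 49.3% of 1.5-fold changes were recovered. That share need not hold for data in which 6074 genes were called.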

Other observations

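The tests of globin slopes, of Y-linked reads in libraries without them, and of the amino acid and fetal gene lists were chosen after the data were examined. So was the fit of genotype within libraries with and without Y-linked reads. The genes named in the next 2 paragraphs were likewise chosen after their values were seen. The other tests were written before their results were seen.

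Some genes of amino acid supply were higher in KO and others were not. Asns, asparagine synthetase, rose 4.27-fold from 81.9 ± 11.5 to 349.7 ± 52.4 CPM (SD, n = 6; adjusted p = 5.87e-09, edgeR), and Psat1 and Mthfd2, of serine and one-carbon metabolism, rose 1.83-fold and 1.93-fold, while Psph fell (log2 fold change -0.29) and Phgdh and Shmt2, at 0.15 and 0.25, did not pass. In a list of 40 genes of the ATF4-driven amino acid response, 18 rose (45%) and 6 fell, among them Trib3 and Atf5; Asns, Psat1 and Mthfd2, which prompted the list, are members of it. The hypothesis that the response rose as a whole needed over 60% and p under 0.05 with an estimated correlation, which was 0.122; with the preset correlation p was 0.000726, not adjusted, at a median log2 fold change of 0.25. The criterion was not met, and whether the response may have risen in part stays open.

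Igf2bp3 and Lin28b, RNA-binding proteins known from fetal blood progenitors, rose 6.18-fold to 17.1 ± 3.06 CPM and 7.19-fold to 5.83 ± 1.09 CPM (SD, n = 6; adjusted p = 2.53e-09 and 3.31e-06, edgeR). Of 16 tested genes of a fetal list 9 rose (56.2%) and 2 fell, Hmga2 and Mycn. Igf2bp3 and Lin28b, whose rise prompted the list, are members of it, so neither this share, which missed the 60% set for it, nor the unadjusted p of 0.0491 with an estimated correlation tests a shared rise of fetal genes independently.

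Of 100 splits of the 12 libraries into 6 and 6, 1, the real one, gave as many as 6074 genes changed, and the highest other gave 397. A share of 1 in 100 is the smallest these splits can give. The other splits mix the genotypes, which widens the spread within groups and lowers their counts. No split can separate genotype from anything that goes with it in these libraries.

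Erythroid genes rose in a gate defined by Sca-1, whose gene Ly6a fell. Carry-over of globin-rich red cells, which the Ter119 depletion and the cKit sort would remove, is a possible explanation. If the carried-over cells were alike in every library, the other erythroid genes would scale with globin with a slope of 1. Over KO libraries, whose globin excess spanned 7.11-fold, the median slope was 0.295, and 0.255 to 0.307 with 1 library left out. Carried-over cells whose globin content differed between libraries, or error in the globin values of these 6 libraries, would also lower the slopes. The slopes therefore do not decide the question. In KO, summed globin stood at 206.9 ± 99.4 CPM (WT 18.9). Tfrc stood at 356 ± 55.8 CPM (WT 104) and Gata1 at 175 ± 34.9 CPM (WT 41.2). Globin-rich cells would add far more globin RNA than Tfrc or Gata1 RNA. These levels argue against carry-over as the main source of the rise of Tfrc and Gata1. Globin reads aligned to several places were left out, which limits this. Epor and Mt2 lay below globin (29.3 and 39.6 CPM in KO). For them and the other erythroid genes carry-over stays open. Late red cell genes had slopes closer to 1: Slc4a1 0.826, Epb4.2 0.728, Alas2 0.728 and Gypa 0.648. A larger share of committed progenitors in the gate stays open too. Of 12 granulocyte and monocyte genes picked from the list of 30 before this test, the median log2 fold change was 0.58, with 7 higher and 1 lower. The whole list, in which 12 rose and 2 fell, had a median of 0.24 and a mean of 0.11 and was not called in the reported test. Its lowest members were Ngp, Camp and Lyz1 (-1.20, -1.13 and -1.12), which did not pass, and Lyz2 (-0.71), which did. Members of the mast cell, basophil and eosinophil list went both ways (Prss34 and Mcpt8 lower, Gzmb, Cma1 and Tpsb2 higher). A change of erythroid expression within LSK cells was not tested and stays open.

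Neighbouring Zfp genes shared a direction more often than in shuffles. Of 175 pairs of Zfp genes within 10 genes of each other, 82.9% shared a direction, above the 66.3% to 77.7% of the middle 95% of 10000 shuffles. Clustered Zfp genes also fell more often, 57.8% of 223 against 33.3% of 111 isolated ones. That difference can raise the share of pairs, so the pairs alone do not show that neighbours change together. A single passenger interval near an allele or transgene could lower linked genes. The Zfp genes that fell lay on 17 chromosomes, and the largest neighbourhood held 18 of 166, or 10.8%, so a single interval does not hold most of them. That count does not weigh the size of the falls and leaves out Zik1, which is not named Zfp. Whether the genes with the largest falls, such as Zik1 and Zfp773, share an interval was not tested. Reads shared between similar Zfp genes were not tested and stay open beside a change of these loci in KO.

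Among libraries without Y-linked reads, Xist was 2.10-fold lower in KO, at 415 ± 38.4 CPM against 873 ± 37.3 CPM (SD, n = 3 each; adjusted p = 0.0112 in an edgeR fit of genotype within libraries with and without Y-linked reads, chosen after seeing the data). In the genotype-only test over all 12 libraries Xist did not pass (adjusted p = 0.714). An exact permutation test, two-sided, gave p = 0.1, the smallest it can give with 3 against 3. Cells with a Y chromosome mixed into these libraries could lower Xist, but Y-linked reads there reached at most 0.0572% of the level in KO libraries with them. Reactivation of the inactive X was tested on 125 X-linked genes: their median log2 difference between the effects in libraries without and with Y-linked reads was 0.0062, within the -0.07 to 0.06 of random lists matched on expression.

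For the genotype effect to differ between libraries with and without Y-linked reads, edgeR called 0 genes, with 1620 at an unadjusted p under 0.05 where chance gives 843, so a difference is not excluded.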
